A study of Mus musculus with 14 samples.

How the data were processed

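RNA from 14 lung tumours of mice was measured by RNA-seq. The tumours came from 2 genetically engineered models of small cell lung cancer (SCLC), a neuroendocrine cancer of the lung. In both models Rb1 and Trp53 are floxed and are deleted in the lung by an adenovirus that expresses Cre recombinase from the Cgrp promoter, which is active in neuroendocrine cells. RPM mice also carry a Cre-activated Myc T58A allele (n = 11), and RPR2 mice carry floxed Rbl2, which encodes p130 (n = 3). By the source names, 9 RPM tumours had 2 copies of the Myc allele (LSL/LSL) and 2 had one copy (LSL/+, replicates 2 and 4). Per the labels' protocols, tumours were cut from the lung by eye, RNA was taken from fresh or frozen tissue, and stranded, poly(A)-selected libraries were sequenced from one end. Groups and allele numbers were taken from the genotype labels and the source names, and each column of the table was matched to a sample by its title.

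The single deposited table holds FPKM values that the authors made for each gene and library, in 46517 rows named by Ensembl gene identifiers and 1 further row for a reporter that is listed at 0 in all 14 libraries and was left out. The submitters' processing notes name RSEM 1.2.12, Bowtie 1.0.1 and the mm10 genome, with no roles or settings. The annotation release, the strand setting and any scaling between libraries are not given in the sources used here. RSEM divides reads that match several genes among them, so values of genes with near-identical copies depend on that division. Symbols were found for 46005 identifiers, and coordinates are those of GENCODE on GRCm38, the same assembly as mm10.

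The table gives no read counts. In short genes with 1 annotated transcript the lowest values fall on steps that correspond to single reads. A search for the read length at which these steps line up best gave 47 to 54 bases in the RPM libraries and 49 to 51 in the RPR2 libraries. The steps correspond to about 17.6 to 19.6 M mapped reads per RPM library and 21.4 to 22.7 M per RPR2 library. At that depth 3 reads on a gene of 2 kb equal an FPKM of 0.0765 to 0.0850 in RPM and 0.0660 to 0.0700 in RPR2, counting error only. These depths are estimates, and no count model was fitted.

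Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 15719 for RPM against RPR2 and 14862 within RPM. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, Benjamini-Hochberg adjustment, threshold 0.05). All 35 gene lists were fixed before the data were examined and tested with camera in limma at the preset inter-gene correlation of 0.01, two-sided, adjusted over the 35 lists. Levels of 8 genes were compared by two-sided exact permutation tests over the 364 splits of the libraries, whose smallest p is 0.00549, with Benjamini-Hochberg adjustment over the 8. Myc by allele was tested over 55 splits, whose smallest p is 0.0364. Relations across the 11 RPM tumours were tested by 100000 permutations. The number of members of a list past the threshold is given over all genes tested and adjusted over the list alone.

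Named genes follow a rule that was also fixed before the data were examined. It takes the 6 design genes, subtype factors (Neurod1, Yap1 and Pou2f3), and the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, skipping unnamed and predicted genes, pseudogenes and immune receptor segments. It adds up to 4 members of each list with the smallest p, or up to 2 where none passed, up to 5 genes per direction for the allele comparison, and genes that stood out by Dixon's ratio. Where a count of 5 or fewer members of a list fell outside the rule, those members are named, chosen after their values were seen. Some genes that the rule takes, or that belong to such a count, and a relation between genes are not reported here, and they stay in the counts and adjustments. A few genes outside the rule appear in the closing section and are said there to have been chosen after their values were seen.

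On simulated values with the means and spreads of the 15719 genes, the test of RPM against RPR2 recovered 34.0% of the genes moved by 1 log2 unit and 86.0% of those moved by 2, out of 200 moved genes, and called 3 genes that were not moved. For LSL/LSL against LSL/+ it recovered 35.0% and 78.0% over 14862 genes and called 8 unmoved genes. With nothing changed neither comparison called a gene or a list. Genes were simulated as independent of each other, with the same spread in both groups. The simulation therefore cannot show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.868 for ribosomal protein genes.

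Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at a mean FPKM of 5, TPM scaling, median-of-ratios scaling, quantile normalization, array weights, empirical Bayes without trend or robust, exact Wilcoxon tests, averaging or a random effect for tumours that share a title number, only LSL/LSL tumours, a covariate for markers of other cell types, each library left out in turn, and for lists an estimated correlation and fry. The covariate was the mean of the 12 lists of other cell types, so each of those lists is part of it. It stood at 3.54, 3.71 and 3.69 in RPR2 and at 2.03 to 3.44 in RPM, without overlap. With it, genotype and other cell types cannot be told apart. Chosen after seeing the data were the addition of processed pseudogenes to their parent genes and the removal of trends with transcript length and GC. Parents of pseudogenes were found with BLAST+ 2.17.0 (90% identity over 50% of the length).

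The library codes of RPM and RPR2 have different prefixes, RPM replicate 9 has one of its own, and no prefix is shared between the models, so a batch of library preparation or sequencing and the genotype cannot be told apart. Titles of 2 pairs of RPM tumours share a number (replicates 6 and 7, replicates 10 and 11), and the labels do not say whether tumours came from separate mice, so p-values measure the spread between tumours. With the shared title number as a random effect the consensus correlation within a pair was 0.762. Replicates 10 and 11 had the highest correlation of any pair of RPM libraries (Pearson r = 0.976 across genes, which are not independent replicates), their values are not identical, and both were kept. Plots were drawn with matplotlib 3.10.9.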

Results

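Gene expression was compared between 11 RPM and 3 RPR2 tumours, which share the loss of Rb1 and Trp53 and differ in a Myc allele and in Rbl2. The comparison asks how SCLC driven by Myc differs from SCLC of the RPR2 model. Each library was estimated to hold 17.6 to 22.7 M mapped reads, and between 12994 and 14974 genes had an FPKM of at least 1.

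The first principal component of the tested genes held 42.1% of the variance and separated the models, with RPM scores of -53.2 to 0.992 and RPR2 scores of 107 to 117. The second held 22.2% and separated RPR2 replicate 3 (118) from RPR2 replicates 1 and 2 (-62.9 and -53.1). RPR2 replicates 1 and 2 correlated at r = 0.960 across genes, which are not independent replicates, and RPR2 replicate 3 correlated with them at 0.754 to 0.777. In RPR2 replicate 3 Sftpc, the alveolar surfactant protein gene, stood at 30744 FPKM, against 709 and 983 in the other RPR2 libraries. The neuroendocrine and synaptic list means there were 1.38 and 0.840, against at least 3.56 and 2.83 in every other library of either model. Values without this library are therefore given where they change a call.

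**Figure D1:**
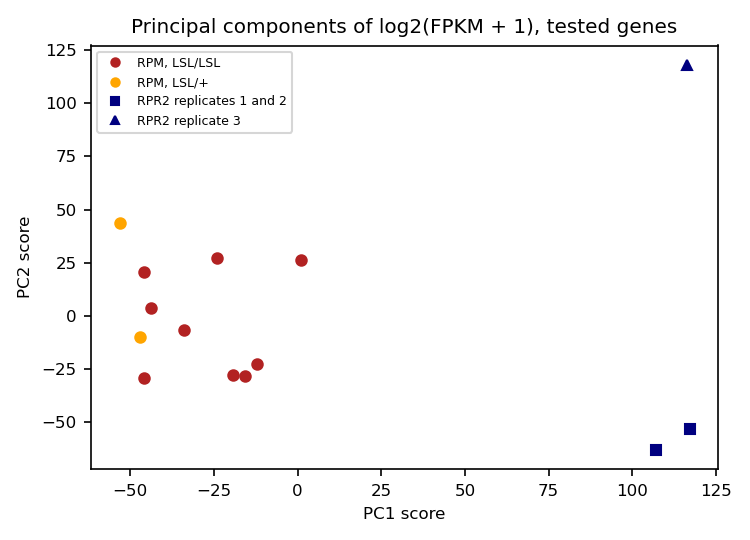
Scores of the 14 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1) over tested genes, one point per library. RPR2 replicate 3 lies at 118 on the second component, away from the other RPR2 libraries at -62.9 and -53.1.

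Myc, at chromosome 15, 61985391 to 61990374 (GRCm38, plus strand, ENSMUSG00000022346), rose 23.4-fold in RPM. It stood at 224 ± 88.7 FPKM (SD, n = 11) in RPM and at 4.68, 6.83 and 13.6 FPKM in the RPR2 libraries, and all 11 RPM tumours lay above all RPR2 tumours. Values summed over the gene do not tell transcripts of the Myc T58A allele from those of the endogenous gene. Two-sided exact permutation gave p = 0.00549, the smallest these 364 splits can give, and 0.0440 after Benjamini-Hochberg adjustment over 8 genes (0.0513 without RPR2 replicate 3, where fewer splits exist). Its paralog Mycl was higher in 2 RPR2 tumours (197 and 69.6 FPKM) than in RPM (10.7 ± 7.64, SD, n = 11) but stood at 4.32 in RPR2 replicate 3, and the difference did not pass (exact permutation p = 0.0659, adjusted p = 0.176). Mycn was at 1.82 ± 1.10 FPKM in RPM and at 1.22, 2.21 and 30.3 in RPR2 (exact permutation p = 0.209, adjusted p = 0.278).

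The deleted tumour suppressors did not differ past the threshold at the level of the whole gene. Rb1 was at 11.3 ± 5.23 FPKM in RPM and at 39.4, 49.8 and 3.58 in RPR2 (exact permutation adjusted p = 0.273), Trp53 at 16.7 ± 20.5 (78.0 in RPM replicate 9) against 10.3, 12.5 and 5.69 (adjusted p = 0.421, same exact test), and Rbl2 at 6.68 ± 1.83 against 3.58, 7.55 and 3.34 (adjusted p = 0.253, same exact test; SD, n = 11 for RPM). Values summed over a gene do not show whether its floxed part is missing, so these levels do not check the deletions. Without RPR2 replicate 3, limma with Benjamini-Hochberg adjustment called Mycl and Rb1 lower in RPM (adjusted p = 0.000694 and 0.00102). By the same test with Benjamini-Hochberg adjustment Mycl was also called without RPM replicate 6 (adjusted p = 0.0474) or RPM replicate 9 (0.0377), and Mycn without RPR2 replicate 1 (0.0266). With all libraries, limma called Mycl after median-of-ratios scaling (Benjamini-Hochberg adjusted p = 0.0472) and quantile normalization (0.0348). The filter at a mean FPKM of 5 (0.0488), array weights (1.98e-05) and pseudogenes added to parents (0.0497) did so too. Mycl was called in 8 of 31 alternatives.

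**Figure D2:**
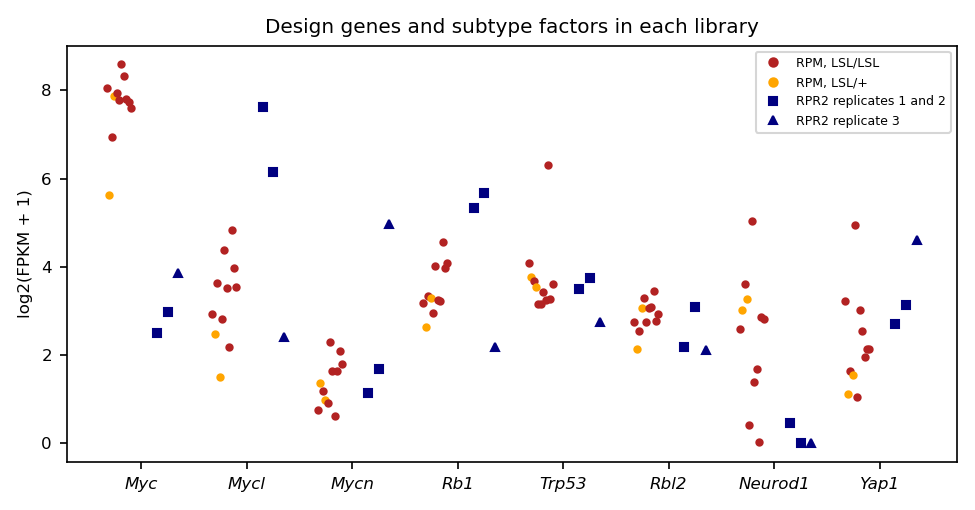
Expression of the design genes and subtype factors as log2(FPKM + 1) (y axis), one point per library, RPM on the left and RPR2 on the right of each gene. All RPM points for Myc lie above all RPR2 points, and RPR2 replicate 3 lies apart from the other RPR2 libraries for Mycl and Mycn.

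Over all tested genes, 2897 rose and 3586 fell in RPM relative to RPR2 (limma, Benjamini-Hochberg adjusted p under 0.05), and 1650 and 2413 of these did so by at least 2-fold. The groups did not overlap for 1745 genes higher and 2133 lower in RPM, where chance gives 0.549% of genes for both directions together. The largest rises included Cplx1, which encodes the presynaptic protein complexin 1 (121 ± 51.1 FPKM in RPM, SD, n = 11, against 0.34, 0.17 and 0.12), the tubulin gene Tubb3 (112 ± 83.7 against 5.99, 1.64 and 0.27), Stmn4, Camkv, Fez1, Dbn1 and Tub. Bcat1, a branched-chain amino acid transaminase, rose by 5.66 ± 0.235 log2 units (SE, n = 11 and 3) and the imprinted gene Ndn by 5.26 ± 0.574. The largest falls were in Sftpa1, Sftpb, Krt8, Krt18, Cldn3, Cldn7, Epcam, Cdh1, Tspan8 and Dpep2. Those of Sftpa1 and Sftpb leaned on RPR2 replicate 3, where Sftpa1 stood at 7512 FPKM against at most 212 in any other library. Without that library the log2 difference of Sftpb was -4.92.

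Without RPR2 replicate 3, 2553 genes rose and 4483 fell, and 2220 and 3099 were called in the same direction in both fits, with none in opposite directions. The median difference of all tested genes was -0.06, and TPM scaling, which gives each library the same total, moved it to -0.23, with 1878 genes higher and 3588 lower. Median-of-ratios scaling moved it to 0.05 and quantile normalization to 0.08, and both turned the balance, with 3361 genes higher and 3250 lower for the first and 3657 higher and 3066 lower for the other.

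All 17 epithelial genes fell in RPM, by a mean of 4.90 log2 units (17 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, adjusted p = 5.73e-12). With an estimated correlation between the genes the adjusted p was 0.418. Krt8, a keratin of simple epithelia, was at 14.4 ± 15.5 FPKM in RPM (SD, n = 11) and at 676, 699 and 467 in RPR2, and the cadherin gene Cdh1 at 5.16 ± 5.55 against 205, 332 and 152. Esrp1, a regulator of epithelial splicing, was at 0.962 ± 1.28 against 74.5, 71.7 and 27.7, and Spint2 at 26.5 ± 11.5 against 339, 393 and 638. Markers of alveolar type 2 cells, which are epithelial, fell with them and are given below.

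Neuroendocrine genes moved in both directions. Of 35 tested, 8 rose and 3 fell (8 and 3 adjusted over the list alone), and the list as a whole did not pass (camera, Benjamini-Hochberg adjusted p = 0.0658, mean 0.59). The reticulon gene Rtn1 (135 ± 70.6 FPKM in RPM, SD, n = 11, against 8.61, 20.7 and 0.51), Tagln3 and Bex1 rose. Foxa2, a transcription factor of lung epithelium, fell from 108, 139 and 60.6 to 31.6 ± 12.1, and Nkx2-1 and Calca fell too. Nkx2-1 was at 69.9, 102 and 309 FPKM in RPR2 and at 62.0 ± 17.0 in RPM, with a range of 41.9 to 95.3. RPR2 replicate 1 thus lay within the RPM range for Nkx2-1, and RPR2 replicate 3 was the highest. The direction of the list rested on RPR2 replicate 3, whose list mean was 1.38 against 6.06 and 6.16. Without it the mean difference was -0.98, with 3 genes higher and 10 lower (camera, Benjamini-Hochberg adjusted p = 0.474). The list was called higher without RPR2 replicate 1 or 2 (camera, Benjamini-Hochberg adjusted p = 0.00372 and 0.00272) and without RPM replicate 5 (0.0299). With an estimated correlation none of these passed (camera, Benjamini-Hochberg adjusted p = 0.749, 0.725 and 0.824, and 0.825 with all libraries). With all libraries and the preset correlation, the list was called higher after TPM scaling (camera, Benjamini-Hochberg adjusted p = 0.0303). It was also called with no filter (0.0215) and with a pseudocount of 0.1 (0.0494).

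Synaptic and axonal genes rose, 11 of 26 with none falling (11 adjusted over the list alone; mean 1.54; camera, Benjamini-Hochberg adjusted p = 0.00213, and adjusted p = 0.640 with an estimated correlation). Besides Cplx1 and Tubb3 these included the microtubule-associated genes Mapt (23.9 ± 11.8 FPKM in RPM, SD, n = 11, against 1.72, 3.27 and 0.15) and Dcx (20.4 ± 16.6 against 0.01, 0.11 and 0.01). Without RPR2 replicate 3 the mean was 0.50, 7 rose and 7 fell, and the list was no longer called (adjusted p = 0.295 by camera with Benjamini-Hochberg adjustment).

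Among the subtype factors, Neurod1 rose in RPM by 2.28 ± 0.785 log2 units (SE, n = 11 and 3; limma, Benjamini-Hochberg adjusted p = 0.0303), at 0.02 to 31.7 FPKM in RPM and 0.38, 0 and 0 in RPR2. The exact permutation test gave p = 0.0275 and an adjusted p of 0.110 over 8 genes, and the limma call was lost without RPR2 replicate 1, 2 or 3 (Benjamini-Hochberg adjusted p = 0.0634, 0.0958 and 0.0742). The covariate for markers of other cell types lowered the Neurod1 difference to 1.16 (limma, Benjamini-Hochberg adjusted p = 0.356), and its call was also lost with only LSL/LSL tumours (0.0615), with no filter (0.0569), by the exact Wilcoxon test (0.0615) and with the title number as a random effect (0.142). The call of Ebf1 was lost with the covariate and the random effect too (limma, Benjamini-Hochberg adjusted p = 0.196 and 0.0668). The covariate did not overlap between the models, so calls lost with it do not tell other cell types from genotype. Yap1 was at 6.01 ± 8.21 FPKM in RPM and 5.52, 7.75 and 23.3 in RPR2 (limma, Benjamini-Hochberg adjusted p = 0.165, and 0.0273 without RPM replicate 5). Pou2f3, the tuft-cell factor, was at 0.0373 ± 0.0364 FPKM in RPM, too low to be tested. Of the 6 proneural genes tested, Neurod1, Ebf1 and Hes6 rose (3 adjusted over the list alone) and Ebf3 was at 2.37 ± 4.30 FPKM in RPM against 0.04, 0.06 and 0.01. The list was not called (camera, Benjamini-Hochberg adjusted p = 0.140). Neither Ebf1 nor Hes6 was called without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.118 and 0.321). Ebf1 was not called without RPR2 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0711), nor Hes6 without RPM replicates 2, 3 or 10 (0.0505 to 0.0516).

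Ribosome biogenesis genes rose together in RPM. Of 36 genes, 34 rose and 1, Utp20, fell (34 and 1 adjusted over the list alone; mean 1.40; camera, Benjamini-Hochberg adjusted p = 1.28e-17, and adjusted p = 0.244 with an estimated correlation). Fbl, the methyltransferase of ribosomal RNA, was at 259 ± 53.0 FPKM in RPM (SD, n = 11) and at 56.2, 42.8 and 73.0 in RPR2. Nolc1, a nucleolar protein gene, was at 80.8 ± 13.3 against 21.6, 20.2 and 12.7, and Nop16 and Grwd1 rose likewise. The list mean was 5.92 ± 0.219 in RPM and 4.55, 4.43 and 4.58 in RPR2, so all 3 RPR2 tumours lay below all RPM tumours, RPR2 replicate 3 included.

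Ribosomal protein genes rose as well, 40 of 43 with none falling (42 adjusted over the list alone; mean 1.43; camera, Benjamini-Hochberg adjusted p = 1.09e-11, and adjusted p = 0.634 with an estimated correlation). Rpl3 was at 1750 ± 338 FPKM in RPM (SD, n = 11) and at 447, 171 and 848 in RPR2, and Rpl5, Rps4x and Rps3 also rose. The list mean in RPR2 replicate 3, 10.04, lay within the RPM range of 9.70 to 10.999, while RPR2 replicates 1 and 2 were at 8.25 and 8.15. Of the 43 members, 8 lay below all RPM tumours in RPR2 replicate 3, the 4 named ones among them, and all 43 in each of the other RPR2 libraries. Many of these genes have processed pseudogene copies, of which Rpl3-ps1 was listed at 0 in all 11 RPM libraries and at 33.5, 293 and 306 FPKM in RPR2.

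Genes of nucleotide synthesis rose, 17 of 24 with none falling over all genes (17 higher and 1, Prps2, lower adjusted over the list alone; mean 0.95; camera, Benjamini-Hochberg adjusted p = 7.41e-08, and adjusted p = 0.175 with an estimated correlation). They included the serine hydroxymethyltransferase gene Shmt2 (117 ± 30.8 FPKM in RPM, SD, n = 11, against 21.1, 17.3 and 21.1), Nme1, Prps1 and Adsl. Among the arginine and polyamine genes 6 rose and 4 fell of 15 (6 and 4 adjusted over the list alone), and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.180, mean 0.22; 0.0332 and mean 0.44 without RPR2 replicate 3, where the adjusted p was 0.314 with an estimated correlation). Those that rose included Srm, spermidine synthase, at 245 ± 41.5 FPKM against 34.5, 19.1 and 32.1, the ornithine decarboxylase gene Odc1 at 140 ± 33.6 against 47.7, 34.3 and 35.8, and Sms and Amd1. Those that fell were Arg1, Ass1, Oaz2 and Sat1, which encodes an acetyltransferase of polyamines.

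Mitotic genes rose, 22 of 30 with none falling (25 adjusted over the list alone; mean 0.86; camera, Benjamini-Hochberg adjusted p = 1.02e-07, and adjusted p = 0.634 with an estimated correlation). Birc5, which encodes survivin, was at 115 ± 19.2 FPKM in RPM (SD, n = 11) and at 45.1, 35.04 and 21.8 in RPR2, and Cenpa, Cdk1 and Bub3 rose. RPR2 replicate 3 had the lowest list mean, 3.75 against 5.20 and 4.92, and without it the mean difference was 0.43, 14 genes rose and the list was still called (camera, Benjamini-Hochberg adjusted p = 5.12e-05). Of 30 DNA replication genes 11 rose and none fell (11 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00432, and adjusted p = 0.634 with an estimated correlation), among them Gins1, Mcm10, Rrm2 and Cdt1. That call was lost without RPR2 replicate 3, where the mean fell from 0.40 to 0.06 and 8 rose and 7 fell (camera, Benjamini-Hochberg adjusted p = 0.233). Pcna of that list has a processed pseudogene copy, Pcna-ps2, which was at 128 ± 41.1 FPKM in RPM and listed at 0 in all 3 RPR2 libraries. Glycolysis genes were at the threshold, with 8 rising and 2 falling of 21 (8 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0495, and adjusted p = 0.640 with an estimated correlation). Eno1, Pgk1, Pgam1 and Pkm were among those that rose, and Aldoc and Slc2a1 fell. Pgam1 has a processed pseudogene copy, Pgam1-ps2, listed at 0 in all RPM libraries and at 22.6, 5.52 and 0 FPKM in RPR2. Leaving out RPR2 replicate 2 ended the list's call (camera, Benjamini-Hochberg adjusted p = 0.334), as did leaving out RPM replicate 1, 2, 4, 5, 7 or 8 (0.0517 to 0.0653) and the title number as a random effect (0.0881).

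Genes of antigen presentation fell in RPM, 11 of 13 with none rising (11 adjusted over the list alone; mean -2.41; camera, Benjamini-Hochberg adjusted p = 1.91e-07, and adjusted p = 0.418 with an estimated correlation). The class I gene H2-D1 was at 160 ± 65.5 FPKM in RPM (SD, n = 11) and at 1883, 1867 and 1588 in RPR2. The immunoproteasome genes Psmb9 (3.92 ± 2.12 against 50.1, 52.1 and 67.9) and Psmb8 and the peptide transporter gene Tap2 fell too. The 3 RPR2 list means were 6.66, 6.66 and 6.62, and those of RPM ran from 3.70 to 5.03. Interferon response genes fell, 16 of 19 with none rising (16 adjusted over the list alone; mean -1.97; camera, Benjamini-Hochberg adjusted p = 2.94e-06, and adjusted p = 0.634 with an estimated correlation), including Irf9, Mx1 and the RNA sensors Ddx58 (1.89 ± 0.713 against 28.3, 25.0 and 5.81) and Ifih1. The interferon list mean in RPR2 replicate 3, 2.36, lay within the RPM range of 0.958 to 2.77, while RPR2 replicates 1 and 2 were at 4.34 and 4.09, and without RPR2 replicate 3 the mean difference was -2.59. The macrophage, neutrophil, T and NK cell and B cell lists did not pass the test beside these (camera, Benjamini-Hochberg adjusted p of 0.815, 0.823, 0.642 and 0.533).

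**Figure D3:**
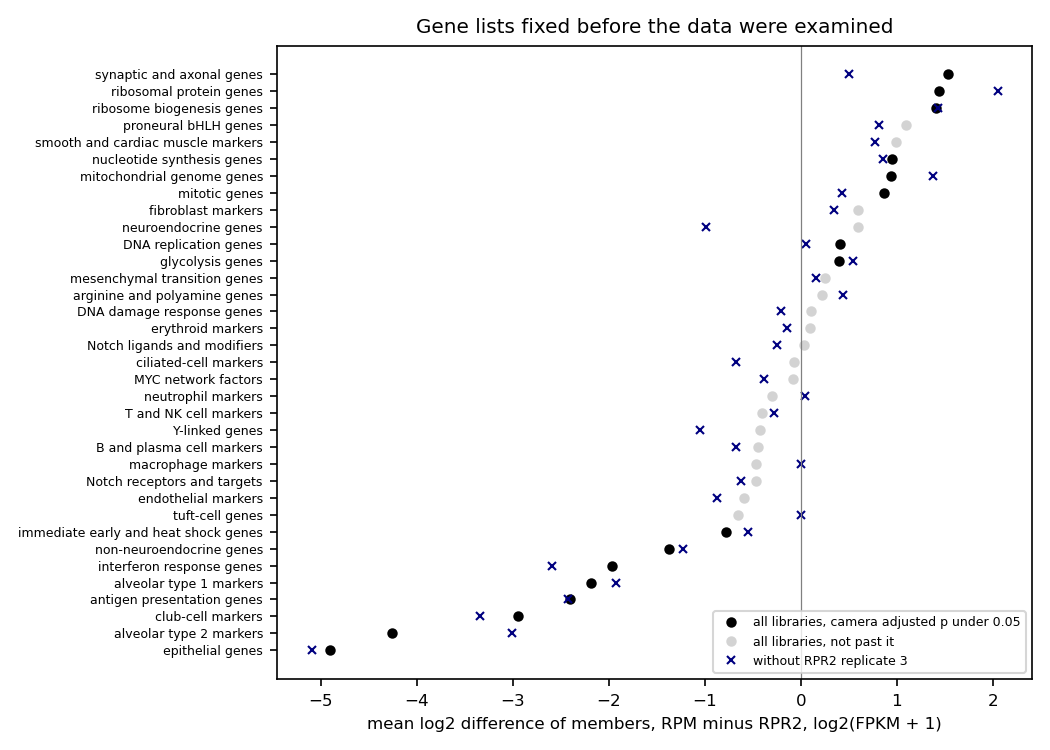
Mean log2 difference (x axis, RPM minus RPR2, log2(FPKM + 1)) of the 35 gene lists (y axis), as black points where camera called the list, grey points where it did not, and crosses for the fit without RPR2 replicate 3. Epithelial genes lie lowest at -4.90, and the neuroendocrine list moves from 0.59 to -0.98 without RPR2 replicate 3.

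Genes known from non-neuroendocrine SCLC fell, 15 of 25 with none rising (17 adjusted over the list alone; mean -1.38; camera, Benjamini-Hochberg adjusted p = 0.000214, and adjusted p = 0.634 with an estimated correlation). Rab27b, Ptges, Abcc3 and Anxa1, the last at 32.5 ± 15.03 FPKM in RPM (SD, n = 11) and 282, 570 and 158 in RPR2, were the most significant. Of 10 Notch receptors and targets, Hes1 (5.25 ± 3.62 against 18.4, 41.5 and 60.5), Notch1, Rest and Nrarp fell and Heyl rose (4 and 1 adjusted over the list alone), with no call for the list (camera, Benjamini-Hochberg adjusted p = 0.468). Heyl, Notch1 and Rest were not called without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0587, 0.0769 and 0.148), nor was Rest without RPR2 replicate 1 (0.0519) or with the title number as a random effect (0.0620). Of 12 Notch ligands and modifiers, Dlk2, Rfng and Mfng rose and Numb and Lfng fell (3 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.533). Among 10 factors of the MYC network, Max, the dimerization partner of Myc, rose (52.1 ± 6.17 against 23.7, 28.1 and 37.2) with Mxi1 and Mxd3, and Mxd1 and Mxd4 fell, so that the family of Myc antagonists went both ways (3 and, with Mlxipl, 3 adjusted over the list alone). The list was not called (camera, Benjamini-Hochberg adjusted p = 0.951), and its mean (-0.08) and the direction of its test (up) differed in sign.

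Of 17 mesenchymal transition genes, Zeb1, Mmp2 and Tgfb2 rose and Tgfb1 fell (3 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.458). Mmp2 and Tgfb2 were not called without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.107 and 0.152), nor was Tgfb2 with the title number as a random effect (0.0553). Of 20 DNA damage response genes, 5 rose, among them Parp1, Xrcc6, Fanca and Fancd2, and Slfn9 fell (1.45 ± 1.01 FPKM in RPM, SD, n = 11, against 65.1, 54.5 and 5.77; 5 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.128). Of 4 tuft-cell genes tested, Dclk1 rose, Ptgs1 and Alox5ap fell, and Sox9 was at 0.722 ± 0.822 FPKM in RPM (1 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.707). Alox5ap was not called without RPR2 replicate 3 and Sox9 was called without RPR2 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0934 and 0.0231).

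Markers of lung epithelium were lower in RPM. Alveolar type 2 markers fell, 10 of 11 (10 adjusted over the list alone; mean -4.26; camera, Benjamini-Hochberg adjusted p = 0.000425, and adjusted p = 0.634 with an estimated correlation), with Sftpb at 38.3 ± 44.3 FPKM in RPM (SD, n = 11) and 212, 497 and 9992 in RPR2, and with Abca3, Lamp3, Etv5 and Cxcl15. Alveolar type 1 markers fell, 7 of 10 (8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00806, and adjusted p = 0.634 with an estimated correlation), with Emp2, Aqp5, Vegfa and Clic5. Club-cell markers fell, 6 of 10 (6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0489, and adjusted p = 0.640 with an estimated correlation), with Gabrp, Hp, Cyp2f2 and Cbr2. Without RPR2 replicate 3 the adjusted p of these lists were 0.0803, 0.157 and 0.118 (camera, Benjamini-Hochberg), with mean differences of -3.01, -1.92 and -3.34 in place of -4.26, -2.19 and -2.95. With the title number as a random effect the alveolar type 1 and club-cell lists were not called (camera, Benjamini-Hochberg adjusted p = 0.0506 and 0.143), nor was Cbr2 (limma, 0.0879). The club-cell call was also lost without RPR2 replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.103) or RPM replicate 2, 7 or 8 (0.0510 to 0.0557). Cyp2f2 and Cbr2 were not called without RPR2 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0698 and 0.120) or RPR2 replicate 2 (0.207 and 0.235), nor Cbr2 without RPM replicate 2, 3, 6, 7 or 8 (0.0517 to 0.0659). Sftpb lost its call without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0515). Ciliated-cell markers were not called (camera, Benjamini-Hochberg adjusted p = 0.946): Fam183b rose, 1 adjusted over the list alone, and Tekt1, Tmem212 and Rsph1 did not pass, with Rsph1 at 2.95 ± 1.61 FPKM in RPM and 10.3, 12.2 and 0.71 in RPR2. In the fit without RPR2 replicate 3 Fam183b was not called and Rsph1 and Tmem212 were called lower (limma, Benjamini-Hochberg adjusted p = 0.139, 0.00230 and 0.0133). Tekt1 was called higher without RPM replicate 2, RPM replicate 4 or RPR2 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0341, 0.0262 and 0.0336).

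Fibroblast markers lay just outside the threshold, with 7 of 12 higher and 2 lower (8 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0503). Fbln1, Col3a1 and Col1a2 rose and Tcf21 and Dcn, which encodes decorin, fell, Dcn from 117, 77.1 and 41.1 to 10.4 ± 8.66 FPKM (SD, n = 11). Of the muscle markers Acta2, Des and Actc1 rose, 3 of 12 (2 adjusted over the list alone), and Myh11 did not pass (camera for the list, Benjamini-Hochberg adjusted p = 0.0552). The fibroblast list was called without RPM replicate 2, 3, 4, 6 or 11 (camera, Benjamini-Hochberg adjusted p = 0.0267 to 0.0483) and the muscle list without RPM replicate 4, 6 or 11 (0.0352 to 0.0483). With an estimated correlation none of these passed (camera, Benjamini-Hochberg adjusted p = 0.604 to 0.670). Of 33 alternatives, 15 called the fibroblast list and 10 the muscle list. With all libraries, the covariate for markers of other cell types called the fibroblast list (camera, Benjamini-Hochberg adjusted p = 0.00512). The fibroblast list is part of that covariate, so this call may be partly built in. No filter called the fibroblast and muscle lists (0.00876 and 0.0110), as did TPM scaling (0.0463 and 0.0260). Actc1 was not called without RPM replicates 1, 2, 3, 6, 7, 8, 10 or 11 (limma, Benjamini-Hochberg adjusted p = 0.0523 to 0.0708) or without RPR2 replicate 1 or 3 (0.110 and 0.214) or with the title number as a random effect (0.0546), and Myh11 was called without RPM replicate 2 (0.0401). Of 13 endothelial markers Vwf (5.63 ± 4.07 against 238, 329 and 28.3) and Tek fell (2 adjusted over the list alone), and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.458). Tek was not called without RPR2 replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.0858 and 0.118). Of 13 macrophage markers Chil3 and Lyz2 fell and Fabp4 rose (2 lower and none higher adjusted over the list alone). Lyz2 was not called without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0731), nor Fabp4 without RPR2 replicate 1 or 2 (0.175 and 0.140) or RPM replicate 1, 7, 8 or 10 (0.0520 to 0.0609). Lck was not called without RPR2 replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.124 and 0.0799). Cd4 rose and Cd2 and Lck fell among 4 T and NK cell markers tested (1 and 2 adjusted over the list alone), Cd79b fell among 6 B cell markers (1 adjusted over the list alone), and none of 6 neutrophil markers and of 4 erythroid markers passed (none adjusted over the list alone; camera for the erythroid list, Benjamini-Hochberg adjusted p = 0.857). Cd79a was called lower without RPR2 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0385). The neutrophil marker Retnlg was called lower without RPM replicate 1 and the macrophage marker Ctss without RPR2 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0109 and 0.0407).

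Of the lists that track handling of the tissue, immediate early and heat shock genes fell, 8 of 16 with 2 rising (8 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0489, and adjusted p = 0.634 with an estimated correlation). Egr1 was at 6.16 ± 2.91 FPKM in RPM (SD, n = 11) and 27.0, 46.2 and 68.6 in RPR2, and Zfp36, Jun and Junb fell, while Nr4a1 and Hsph1 rose. Without RPR2 replicate 3 the list was not called (camera, Benjamini-Hochberg adjusted p = 0.421), nor without RPM replicate 7, 8 or 9 (0.0510 to 0.0550) or with the title number as a random effect (0.122). Genes of the mitochondrial genome rose as a list (camera, Benjamini-Hochberg adjusted p = 0.0253, and adjusted p = 0.640 with an estimated correlation), 2 of 13 singly, mt-Nd1 and mt-Nd2 (none adjusted over the list alone). Without RPR2 replicate 3 the mean difference went from 0.93 to 1.37 and 7 rose singly (camera, Benjamini-Hochberg adjusted p = 0.00113), with mt-Nd4 and mt-Co3 newly called (limma, Benjamini-Hochberg adjusted p = 0.0224 and 0.00297). With an estimated correlation the list did not pass there (camera, Benjamini-Hochberg adjusted p = 0.686). Without RPM replicate 6 mt-Nd4 was called too (limma, Benjamini-Hochberg adjusted p = 0.0381). Median-of-ratios scaling and quantile normalization ended the list's call (camera, Benjamini-Hochberg adjusted p = 0.0680 and 0.487), as did leaving out RPR2 replicate 1 or 2 (0.193 and 0.0874), the title number as a random effect (0.0506) and the covariate for markers of other cell types (0.101). Without RPR2 replicate 1 or 2 mt-Nd1 (limma, Benjamini-Hochberg adjusted p = 0.272 and 0.141) and mt-Nd2 (0.175 and 0.117) were not called, nor was mt-Nd1 without RPM replicate 1, 2, 3, 4, 7, 8 or 11 (0.0507 to 0.0646). Nuclear copies of mitochondrial genes held more of the summed FPKM than the mitochondrial genome in all 14 libraries. In RPM replicate 4 they held 8.70% against 5.56%, and in RPR2 replicate 1 2.38% against 2.05%. Values of mitochondrial genes therefore depend on how reads were divided among copies. The 4 Y-linked genes did not differ past the threshold (none adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.895).

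**Figure D4:**
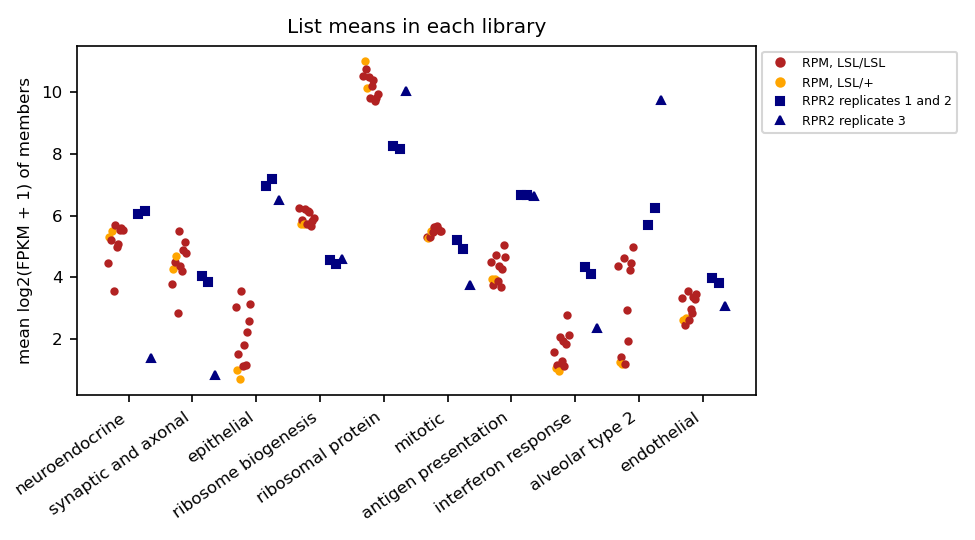
Mean log2(FPKM + 1) of the members of 10 gene lists (y axis), one point per library, RPM on the left and RPR2 on the right of each list. The ribosome biogenesis means of RPR2 (4.43 to 4.58) lie below those of RPM (5.66 to 6.26), and RPR2 replicate 3 lies apart from the other RPR2 libraries for the neuroendocrine, synaptic and alveolar type 2 lists.

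Within RPM, tumours with 2 copies of the Myc allele were compared with those with one. Myc was at 243 ± 74.7 FPKM in LSL/LSL tumours (SD, n = 9, range 123 to 384) and at 48.4 and 234 FPKM in the LSL/+ tumours (replicates 2 and 4). Replicate 2 lay below all 9 LSL/LSL tumours and replicate 4 within their range. The difference did not pass (two-sided exact permutation p = 0.218, smallest possible 0.0364). Pard6a, a gene of the cell polarity complex, was the one gene that differed, at 14.2 ± 2.01 FPKM in LSL/LSL and 40.8 and 38.0 in LSL/+ (limma, Benjamini-Hochberg adjusted p = 0.0306). No gene was higher in LSL/LSL by limma, 2569 genes had an unadjusted p under 0.05 in either direction, and the exact Wilcoxon test, whose smallest p is 0.0364, called 0 and could call none unless most genes reached that p. Rasl11b, Usp46, Eya4, Aif1l and Tbx15 had the smallest p of the genes with a higher mean in LSL/LSL, and Kcnj8, Drg1, Map4 and B230206L02Rik followed Pard6a among those with a lower mean, all at an adjusted p of 0.160 (limma, Benjamini-Hochberg). With 2 LSL/+ tumours the comparison rests on few samples, and it called 8 genes without RPM replicate 4, 3 without RPM replicate 3, 2 without RPM replicate 8 and 0 without RPM replicate 1, 2, 6, 7, 9, 10 or 11. Pard6a was not among those called without RPM replicate 4 (limma, Benjamini-Hochberg adjusted p = 0.0636), where Map4 was (0.0336). It kept its call in 10 of 25 alternatives. Without RPM replicate 2 or 4 a single LSL/+ tumour is left, which is assumed to vary like the LSL/LSL tumours.

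Relations between Myc and neuroendocrine genes were measured across the 11 RPM tumours, with p-values adjusted over 4 relations, of which 3 are given. Myc and the neuroendocrine list mean had r = -0.215 (permutation p = 0.467, adjusted p = 0.623 by Benjamini-Hochberg) and rho = -0.536 (permutation p = 0.0938, adjusted 0.183), and r = -0.329 without replicates 2 and 3. Myc and Neurod1 had r = -0.335 (permutation p = 0.315, adjusted 0.623) and rho = -0.582 (permutation p = 0.0651, adjusted 0.183), and r = -0.330 without replicates 2 and 3. The neuroendocrine list mean and that of Notch receptors and targets had r = -0.769 (permutation p = 0.00611, adjusted 0.0244) and rho = -0.482 (permutation p = 0.137, adjusted 0.183). Without replicates 5 and 1, r was -0.314 (permutation p = 0.418), so that relation rests on those tumours. Without replicate 5 alone r was -0.53 (permutation, Benjamini-Hochberg adjusted p = 0.477), and without replicate 1 alone -0.75 (adjusted p = 0.0857). RPM replicate 5 had the lowest neuroendocrine mean (3.56) and the highest Notch mean (2.99) of the 11. RPM replicate 9 is the only RPM library with its own code prefix, so no relation within a second code prefix could be given.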

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

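Among the 9 LSL/LSL tumours, 171 named genes and 35 list means were examined for 1 tumour that stood apart, by the gap to its nearest neighbour divided by the range, against Dixon's 95% critical value. The rule was fixed before the data were examined. Chance flags about 1 in 20, and 14 of 206 passed, of which 13 are given. Values below are log2(FPKM + 1) or FPKM where stated, and no explanation was tested for them.

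RPM replicate 9 had the highest Trp53, 78.0 FPKM, with a gap of 0.702 of the range. It also had the highest Acta2 at 140 FPKM (0.615), the lowest Nop16 at 55.0 FPKM (0.510) and the lowest Kcnj8 at 1.06 FPKM (0.568).

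RPM replicate 5 had the lowest Cplx1, a gene of neurons, at 18.0 FPKM (0.632). It had the highest Notch1 at 4.82 FPKM (0.658), the highest Rasl11b at 18.6 FPKM (0.512) and the highest mean of the immediate early and heat shock genes, 3.73 against 2.55 to 3.14 in the others (0.505). This is also the tumour with the lowest neuroendocrine list mean.

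The macrophage marker Fabp4 was highest in RPM replicate 3 at 225 FPKM (0.595) and the neutrophil marker Retnlg in RPM replicate 1 at 4.83 FPKM (0.748). RPM replicate 6 had the highest Cd79b at 3.95 FPKM (0.579) and the lowest Xrcc6 at 38.4 FPKM (0.503). Drg1 was highest in RPM replicate 11 at 60.7 FPKM (0.575).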

How the results depend on the processing

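The settings other than the addition of pseudogenes to parents and the removal of length and GC trends were chosen before the data were examined. Of 16 lists called, 8 kept their call under every alternative but the estimated correlation (antigen presentation, epithelial, interferon response, mitotic, non-neuroendocrine, nucleotide synthesis, ribosomal protein and ribosome biogenesis genes). With an estimated correlation 0 lists were called higher and 0 lower, and the smallest adjusted p of camera with Benjamini-Hochberg adjustment was 0.175. With each library left out none was called at an estimated correlation either (smallest adjusted p 0.106). Depth was only estimated, so counting error in low genes was not modelled. No paired analysis was possible because the labels give the tumours of the 2 models no shared numbers. Where no cause is named below, the cause was not tested.

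Genes higher in RPM numbered 1878 with TPM scaling and 1809 with the covariate for markers of other cell types. Genes lower numbered 2171 with a filter at a mean FPKM of 5, which tests fewer genes (10426), 6577 with array weights and 2052 with the covariate. Those at least 2-fold lower numbered 1377 with that filter and 1575 with the covariate. Lists called lower numbered 5 with the title number as a random effect, 5 with the covariate, and 4 to 8 with each library left out. Of the named genes 24 lost their call with the covariate, 19 by the exact Wilcoxon test, 10 with no filter and 13 without RPR2 replicate 3, where 7 gained one. The covariate did not overlap between the models, so the calls it ended do not measure the part of other cell types. After removal of length and GC trends 3923 genes were higher and 3362 lower, and with pseudogenes added to parents 2802 and 3560.

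The Myc difference stayed between 4.24 and 4.93 log2 units with each library left out, 4.49 with tumours of a shared title number averaged and 4.75 with only LSL/LSL tumours. Its adjusted p then exceeded 0.05 because fewer splits exist. Myc in LSL/LSL minus LSL/+ ran from -0.011 (without RPM replicate 2) to 2.24 (without RPM replicate 4).

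Genes that differed by allele numbered 5 and 10 with pseudocounts of 0.1 and 0.01, 30 with no filter, and 0 with TPM scaling, quantile normalization, array weights, empirical Bayes without trend, averaging and the covariate, and 0 to 8 with each tumour left out. The 0 of the exact Wilcoxon test shows nothing here, since too few splits exist for it to call a gene unless most genes reach its smallest p.

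The neuroendocrine and Notch means had r = -0.71 and -0.70 with pseudocounts of 0.1 and 0.01, -0.36 after TPM scaling, -0.91 and -0.89 after median-of-ratios scaling and quantile normalization (permutation, Benjamini-Hochberg adjusted p = 0.00096 and 0.0041), and -0.87 to -0.53 with each tumour left out, the weakest without RPM replicate 5. Myc and the neuroendocrine mean had r = 0.098 after TPM scaling and -0.38 after median-of-ratios scaling.

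The reversals concerned lists and genes that were not called. Array weights gave mean differences of -0.89 for neuroendocrine genes, -0.31 for MYC network factors, -0.062 for tuft-cell genes, -0.86 for ciliated, 0.24 for macrophage, -0.17 for neutrophil and -0.075 for T and NK cell markers, 0.40 for Y-linked genes, and differences of -0.020 for Trp53, -0.0055 for Rbl2, 0.15 for Ctss, 0.35 for Uty and 0.46 for Eif2s3y. For MYC network factors the direction of the test also turned with pseudocounts (-0.14 and -0.15), averaging (-0.11), the random effect (-0.11) and fry (-0.084), and the mean was 0.044 with the mean filter. The mean filter gave -0.14 for Notch ligands and modifiers and 0.087 for mesenchymal transition genes. No filter gave -0.22 for tuft-cell genes and -0.28 for ciliated-cell markers, which fry put at -0.076, quantile normalization at 0.074 and removal of length and GC trends at -0.047. That removal gave 0.084 for erythroid markers, and quantile normalization -0.13 for mt-Nd4. The covariate gave -0.077 for endothelial, 0.27 for macrophage and 0.50 for neutrophil markers, 0.034 for Tmem212, 0.029 for Ctss and 0.086 for S100a8. These lists and genes are part of the covariate, so their changes may be partly built in. In camera the direction is relative to all other genes, while fry tests a list against no change.

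With each library left out, the values ran from -1.23 to 0.042 for Cd79a, -0.11 to 0.69 for Hbb-bs, -0.038 to 0.43 for Hbb-bt, -0.91 to 0.63 for Uty and -1.54 to 1.02 for Eif2s3y. List means ran from -0.98 to 1.40 for neuroendocrine genes, -0.38 to 0.069 for MYC network factors, -1.03 to 0.0065 for tuft-cell genes, -0.67 to 0.39 for ciliated, -0.84 to 0.0055 for macrophage and -0.59 to 0.038 for neutrophil markers, and -1.05 to 0.76 for Y-linked genes. One end of each of these ranges came from the fit without RPR2 replicate 3.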

Other observations

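The tests of lung tissue and of a swap for RPR2 replicate 3 and the 3 relations within RPM tumours were chosen only after the values they use were seen. Genes named here beyond those of the report were also chosen after their values were seen.

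A set of genes was higher in RPR2 replicate 3 than in any of the other 13 libraries. Dlk1 was at 2227 FPKM against at most 24.2 in the other 13 libraries, with its imprinted neighbours Meg3 at 648 (at most 31.1 elsewhere) and Rian at 738 (at most 94.7 elsewhere) on chromosome 12. Apoc1 (1626 against at most 13.9), Trf (6712 against at most 240), Ly6d, Pla2g1b and Ctse were high, and Nkx2-1, the lung lineage factor, stood at 309 FPKM against 41.9 to 102 elsewhere. Hnf4a, a factor of gut and liver, was at 19.3 FPKM against at most 0.15 in RPM, and Gata6 at 22.3 against at most 1.60 in RPM. Another imprinted locus also differed: Igf2 was at 36.2 and 165 FPKM in RPR2 replicates 1 and 2, at 2.70 in RPR2 replicate 3 and at 2.47 ± 2.43 (SD, n = 11) in RPM, while H19 was at 24.2 ± 28.4 in RPM and at most 0.58 in RPR2.

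RPM replicate 9, which had the highest Trp53, had Cdkn2a at 1.93 FPKM, where the other 13 libraries ranged from 36.8 to 399. Cdkn2a encodes p16 and p19Arf, which restrain the cell cycle upstream of Rb1 and p53.

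Lung tissue around the tumour would raise all lung cell types in RPR2 replicate 3. Of 12 lists of other cell types, 5 had a higher mean there than in both other RPR2 libraries: alveolar type 2 (9.73 against 5.69 and 6.25), alveolar type 1 (5.56 against 4.64 and 4.90), macrophage (5.62 against 4.48 and 3.93), neutrophil (2.50 against 1.24 and 1.71) and T and NK cell markers (1.80 against 1.72 and 1.18). The other 7 were lower, among them the endothelial (3.05 against 3.97 and 3.80), fibroblast (2.62 against 3.44 and 3.31) and ciliated means (0.637 against 2.09 and 2.77), a median shortfall of -0.75 for these 3. Lists that move apart in this way argue against lung tissue as the whole source, while a larger share of alveolar cells or of macrophages alone stays open. A library without Rb1-deleted tumour cells was predicted to have little Cdkn2a, yet it was the highest of all at 399 FPKM, 207 times the lowest other library, which is RPM replicate 9, and above the next highest at 177. A swap with an RPM tumour is argued against by Myc at 0.282 of the lowest RPM value. RPR2 replicate 3 also had the lowest neuroendocrine and synaptic list means of all libraries, 1.38 and 0.840, against at least 3.56 and 2.83 elsewhere. Nkx2-1 of the neuroendocrine list was nonetheless highest there. A tumour of another lineage, or a label from outside the series, may account for this library and stays open, and no biological explanation was tested.

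Ribosomal protein genes rose by a mean of 1.43 log2 units. Adding processed pseudogenes to their parents left 1.41, so reads shared with them do not account for the rise. Removing trends with transcript length and GC left 1.49, so a smooth trend over all genes does not account for it either. An effect confined to genes of like length and expression is not excluded by that removal. Quantile normalization lowered it to 0.925 and median-of-ratios scaling gave 1.55, so scaling between libraries may account for part of it. Random lists matched on expression and length rose as well, by a mean of 0.697 over 10000 lists. Only the 43 members were kept out of the draw, so ribosomal protein genes not on the list could be drawn. How far unrelated genes of like expression and length share the rise therefore stays open. None of the random lists reached the observed mean, and the highest was 1.35. Their genes were drawn singly, while the estimated correlation within the ribosomal protein list was 0.868. Means of correlated genes vary more, so that count does not measure chance. The rise was mainly relative to RPR2 replicates 1 and 2, since the list mean of RPR2 replicate 3 lay within the RPM range and 8 of 43 members lay below all RPM tumours there. The Myc allele, the floxed Rbl2 and a batch of library preparation, which coincide with the groups, stay open.

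Ribosome biogenesis genes rose by a mean of 1.40 log2 units. The rise was 1.403 with pseudogenes added to parents, 1.57 with length and GC trends removed and at least 1.51 under median-of-ratios and quantile scaling, which argues against these as its cause. Matched random lists rose by a mean of 0.275, and of 10000 lists 0 reached the observed mean, the highest being 0.846. Their genes were drawn singly, while the estimated correlation within the ribosome biogenesis list was 0.346. Means of correlated genes vary more, so that count does not measure chance. The Myc allele is a candidate explanation that the design names, but floxed Rbl2 and a batch differ between the same groups. Across the 11 RPM tumours Myc and the list mean had r = 0.49 (permutation p = 0.111, adjusted p = 0.111 by Benjamini-Hochberg over 3 relations) and rho = 0.509 (permutation p = 0.114), and r = 0.612 without replicates 2 and 3, which does not decide the point.

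A hypothesis was that the remaining epithelial expression in RPM tumours may follow lung tissue in the piece. The epithelial list mean and the alveolar type 2 mean had r = 0.942 over the 11 RPM tumours (permutation p = 6.0e-05, adjusted p = 0.00018 by Benjamini-Hochberg) and rho = 0.945 (permutation p = 5.0e-05), and r = 0.927 without replicates 11 and 6, which is in line with it. A second was that antigen presentation genes may follow macrophages. Their means had r = 0.805 (permutation p = 0.00366, adjusted p = 0.00549 by Benjamini-Hochberg) and rho = 0.755 (permutation p = 0.00954), and r = 0.794 without replicates 4 and 8. Neither pair of lists shares a gene. Among RPM tumours Sftpc ranged from 1.62 to 615 FPKM and Lyz2 from 110 to 581. Antigen presentation genes are expressed by many cell types, so the relation does not single out macrophages. Both relations were found in the data they were tested on, and averaging tumours of a shared title number gave r = 0.939 and 0.785 over 9 samples.

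Other splits of the 14 libraries into 11 and 3 were refitted for the counts of genes. Of 100 splits, the real one included, 1 gave as many genes higher as the real split (2897, highest other 1081). For genes lower it was also 1 (3586, highest other 1434), for those at least 2-fold higher 1 (1650, highest other 480). For those at least 2-fold lower it was 1 too (2413, highest other 1061). A random grouping thus seldom gave such counts, but only 100 of the 364 splits were refitted, so chance is not excluded. All other splits put RPR2 tumours in a group with RPM tumours, which widens the spread within groups. The splits do not separate genotype from batch.

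The pseudogenes Pcna-ps2 and Rpl3-ps1 split completely between the models. The limits below were applied to all genes of a type, tested or not. Among processed pseudogenes, 492 of them tested, 3 were at or below 0.05 FPKM in one model and at or above 5 in the other. These were chosen on RPM and RPR2 replicates 1 and 2, and 2 of the 3 met the same limits in RPR2 replicate 3. The third, Pgam1-ps2, was listed at 0 in RPM and at 22.6, 5.52 and 0 FPKM in RPR2. It was not among the tested pseudogenes, since it reached an FPKM of 1 only in RPR2 replicates 1 and 2. Among protein-coding genes, 13660 of them tested, 4 met the same limits, Camkv, Gm10184, Gm11273 and Neurog3. They stood at 0.11, 5.05, 16.6 and 0 FPKM in RPR2 replicate 3, so that none of the 4 met the limits there. Neurog3 was not among the tested genes, for the same reason as Pgam1-ps2. Predictions for technical explanations of this pattern were written first and withdrawn after these counts were seen, because only 3 pseudogenes met the limits, so no explanation is weighed.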
